A study of Homo sapiens with 17 samples.

How the data were processed

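Total RNA from xenograft tumours of LNCaP cells (FGC clone) was enriched for polyadenylated mRNA with oligo-dT beads and primed with random hexamers, per the labels' protocols. The cells had been injected under the skin of male NOG mice in a mix of medium and basement membrane gel, and the KO cells were a stable monoclonal line, per the labels' protocols and the series text. The deposited table held raw read counts per gene, whole numbers for 54628 genes named by symbol in 17 libraries. Trimmomatic, HISAT2 and featureCounts, and the builds GRCm38 (mm10) and GRCh38 (hg38), were named in the submitters' processing notes without versions. The series text states that mouse reads were removed before analysis, and how this was done was not given in the sources used here. The strand setting of the counting, the gene annotation and the treatment of reads that match several genes were not given either. Counts of overlapping and antisense genes, and the split of reads among near-identical genes, are therefore uncertain. All columns were matched to samples by name, and 0 per-sample columns were left unmapped.

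Groups followed the sample labels, 10 WT and 7 KO libraries, although the series text gives 9 WT and 8 KO tumours. Replicate names were not shared between the groups and no batch was labelled, so no pairing or batch term was used. Each library is a separate tumour, and because the KO tumours come from 1 clone, p-values measure the spread among tumours of that clone and of the parental line. The library labelled WT A12 stayed in its group in all tests, and the counts of changed genes are also given without it, for a list where they moved by over 1.5 times. Total counts per library ran from 25137556 to 50666343. A gene without a count was given a floor of 3 counts, which corresponds to 0.0596 CPM in the deepest library and 0.118 CPM in the shallowest. Floors cover counting error only. No pair of libraries of a group matched within sampling noise: chi-square over degrees of freedom was at least 23.3 over 45 WT pairs and 40.0 over 21 KO pairs, among genes with at least 20 counts.

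Analysis was run in R 4.3.3. Genes were kept by the default edgeR filter by group (18061 of 54628), libraries were scaled by TMM factors, and KO was compared with WT by edgeR 4.0.16 (robust quasi-likelihood F test, default prior count). A prior count of 2 was used only for log2 CPM values, as in the principal components and list tests. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called changed at an adjusted p under 0.05. Counts over 2-fold also required an absolute log2 fold change over 1. The SE of a log2 fold change was its absolute value divided by the square root of F. The common biological coefficient of variation was 35.9%, and 32.4% without the library labelled WT A12. CPM used TMM-scaled library sizes. In simulated counts with the means and library sizes of these samples (17620 genes, 100 genes changed by each size), the same steps recovered 79 of 100 genes changed by 1 on the log2 scale and 98 of 100 changed by 2, with 12 false calls among 189 (6.35%). The changed genes were drawn from those with a mean of at least 1 CPM. They were far fewer than the genes called in the data, so these rates need not carry over to all tested genes.

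Gene lists were fixed before the data were examined. The 36 lists covered androgen response, androgen-repressed genes, STAT3 targets, JAK-STAT components, interferon-stimulated genes, MHC class I presentation, NF-kB targets, S phase, G2 and M phase, hypoxia and glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, MYC targets, cholesterol synthesis and fatty acid synthesis. They also covered the ATF4 response, the unfolded protein response, heat shock proteins, p53 targets, immediate early genes, neuroendocrine, luminal and mesenchymal genes, steroid metabolism, NRF2 targets, PI3K and FOXO signalling, olfactory receptors, G protein and cAMP signalling and markers of 7 host cell types. The 32 lists with at least 5 tested members were tested with camera from limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the lists. Some genes belong to several lists. Counts of members use calls over all genes, and calls adjusted over the list alone are given beside them. Genes were named by a rule fixed in advance. It took OR51E2 in every library, 9 genes chosen for the study's theme, and the 8 largest changes each way among called genes with a symbol (placeholder identifiers excluded) and at least 5 CPM in the higher group. It also took the 5 smallest adjusted p-values each way under the same conditions, and up to 4 called members of each list, with both directions where members went both ways. Some genes that the rule takes are not reported here. Genes named outside the rule are marked as chosen after their values were seen.

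Alternatives were DESeq2 size factors, upper quartile factors, no filter, a filter of at least 1 CPM in 7 libraries, DESeq2 1.42.0, limma voom with quality weights, the log2 total count as a covariate, and leaving out each library in turn. For lists they were an estimated correlation and fry, which asks whether a list's genes move one way on balance. A fit without WT A5, A7, A12 and KO A18 was added after seeing the data. Single values per library, such as the total count and the mitochondrial share, were compared by two-sided exact permutation tests over 19448 arrangements. Principal components were computed on log2 CPM of the tested genes. The groups were also compared with other splits of the 17 libraries into 10 and 7, 100 splits in all with the real one. Coordinates are from the NCBI gene table of GRCh38.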

Results

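RNA was sequenced from 17 xenograft tumours of LNCaP cells, an androgen-sensitive human prostate cancer line, grown under the skin of male immunodeficient NOG mice to a volume of 1000 mm3. The labels placed 10 libraries in the wild-type group (WT) and 7 in a group carrying a knockout (KO) of OR51E2, an olfactory receptor gene expressed in prostate epithelium. The KO cells were 1 monoclonal line. The series text counted 9 WT and 8 KO tumours, and groups here follow the sample labels. Gene counts summed to 25137556 to 50666343 per WT library and 31901700 to 46775167 per KO library (two-sided exact permutation test, p = 0.633). The comparison of KO with WT asked how loss of OR51E2 altered gene expression in the tumours, and the series title names STAT3. Values below are CPM (read counts relative to the scaled library size), mean ± SD over 10 WT and 7 KO libraries, unless a library is named. Fold changes are KO over WT on the log2 scale with their standard error (SE), adjusted p-values are from edgeR's quasi-likelihood test, and amounts by which a gene rose or fell are on the same log2 scale.

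OR51E2 (chromosome 11, 4680171 to 4697853, GRCh38, protein coding) was lower in KO, from 27.1 ± 16.6 to 6.59 ± 3.61 CPM (log2 fold change -2.04, SE 0.46, adjusted p = 0.00310). The KO libraries still held 93 to 420 OR51E2 counts each. Their levels were 5.91 CPM in A13, 2.81 in A14, 4.39 in A15, 8.24 in A16, 8.69 in A17, 12.9 in A18 and 3.17 in A1. In the WT libraries the level was 11.7 CPM in A2, 31.4 in A3, 44.4 in A4, 57.5 in A5, 23.8 in A7, 35.0 in A8, 4.28 in A9, 12.9 in A10, 35.0 in A11 and 15.5 in the library labelled WT A12. The groups therefore overlapped, with WT A2, A9 and A10 at or below the level of KO A18. The part of OR51E2 altered by the knockout was not given in the sources used here, so transcripts that remain do not by themselves test the labels. The fall did not stop at OR51E2: each of the 5 other tested genes within 100 kb was also lower in KO, with a median log2 fold change of -2.40. OR51E1, a neighbouring olfactory receptor gene also expressed in prostate, fell from 64.0 ± 37.7 to 4.09 ± 2.33 CPM (log2 fold change -3.97, SE 0.54, adjusted p = 7.1e-05). OR51D1, the pseudogene OR51A9P, the noncoding LOC105376528 and TRIM68, a ubiquitin ligase gene, were singled out after their values were seen, and their log2 fold changes were -4.82 (SE 0.98), -2.39 (SE 0.38), -1.94 (SE 0.49) and -0.40 (SE 0.10), with adjusted p from 1.3e-04 to 0.00553. OR51D1 was at 0.510 CPM in WT and 0.0143 in KO, below the floor of 3 counts, so the size of its fall is uncertain. LOC105376528 was also low, at 1.27 and 0.328 CPM. Among 11 tested genes 100 kb to 1 Mb away, 2 were lower and 2 higher, and the median log2 fold change was -0.21.

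**Figure D1:**
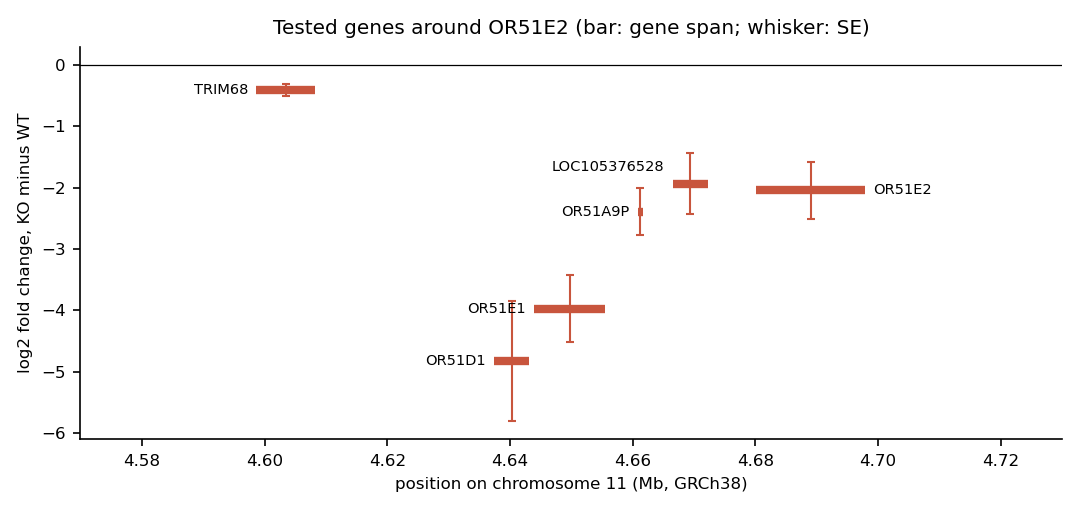
Log2 fold change (KO minus WT, y axis) of the tested genes within 100 kb of OR51E2 against position on chromosome 11 (Mb, GRCh38, x axis). Thick bars span the gene and thin whiskers show the SE, and OR51E2 with its 5 neighbours all lie below 0, from -4.82 for OR51D1 to -0.40 for TRIM68. OR51D1 was at 0.510 CPM in WT and 0.0143 in KO, so the size of its fall is uncertain.

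Over all tested genes, though not for each of them, the library labelled WT A12 lay with the KO libraries. The first principal component of log2 CPM carried 46.4% of the variance and placed A12 at 61.5, the 7 KO libraries between 62.7 and 88.9 and the other 9 WT libraries between -77.3 and -55.3. ETV1, an ETS transcription factor gene that is rearranged in LNCaP cells, was at 0.0611 CPM in A12, at 0.139 ± 0.101 in KO and at 584 on average in the other WT libraries. KLK3, which encodes prostate-specific antigen, stood at 167 CPM in A12 against 159.8 ± 93.6 in KO. For MT1G, a metallothionein gene, A12 was between the groups, at 6.70 CPM against 32.1 on average in the other WT libraries and 0.0169 ± 0.0288 in KO. The label was kept.

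**Figure D2:**
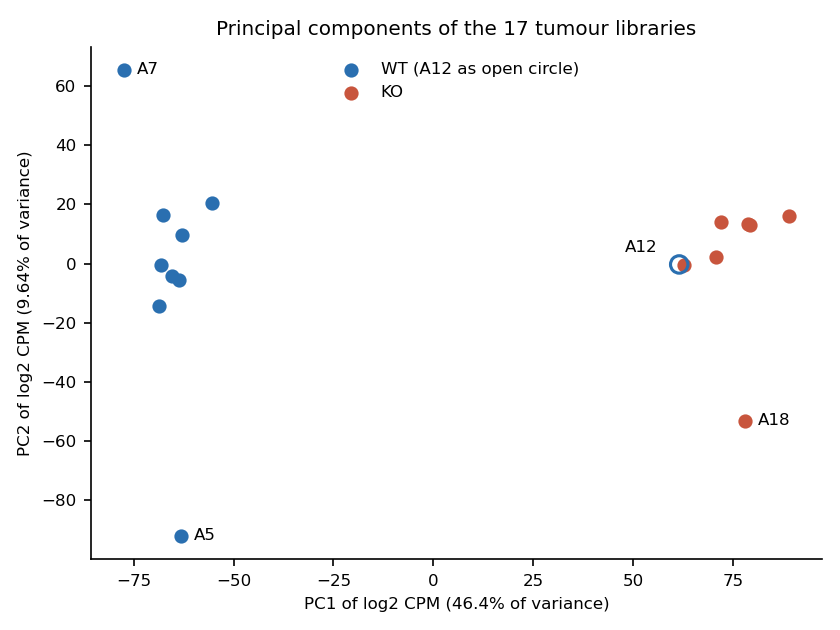
First (x axis, 46.4% of variance) and second (y axis, 9.64% of variance) principal components of log2 CPM, one point per library, WT in blue with the library labelled WT A12 as an open circle and KO in red. The 9 other WT libraries sit at -77.3 to -55.3 on the first component, while A12 at 61.5 sits next to the KO libraries, and WT A5, WT A7 and KO A18 stand apart on the second.

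The tumours of the groups differed widely. Of 18061 genes tested, 5563 changed, 2735 higher and 2828 lower in KO, and 2314 of them by more than 2-fold (966 higher, 1348 lower). Without the library labelled WT A12 the counts were 6441 of 17876 genes (3143 higher, 3298 lower), 2704 of them over 2-fold. With WT A5, WT A7 and KO A18 left out as well, a choice made after seeing the data, 7440 genes changed. The KO tumours came from 1 clone, so these tests measure the spread among tumours and not among knockout clones. Several genes had high counts in the WT libraries other than A12 and few or none in KO. In the library labelled WT A12, ERVMER34-1 and MAGEA8 had no count, CWH43 had 1, ETV1 2, H2AJ 6, MAGEA4 22, RIPOR2 36 and MT1G 219. ERVMER34-1, an endogenous retroviral envelope gene, had 16.4 CPM in WT and no count in any KO library, at least 1449-fold lower by a floor of 3 counts over the group. ETV1 fell from 525 ± 192 to 0.139 ± 0.101 CPM (log2 fold change -11.79, SE 1.20, adjusted p = 1.1e-05). H2AJ, a histone H2A variant gene, fell from 239 to 0.0798 CPM (log2 fold change -11.45, adjusted p = 1.2e-05), with fold changes of -12.04 without KO A13 and -12.35 without KO A17. MT1G fell from 29.6 to 0.0169 CPM (log2 fold change -10.65, adjusted p = 1.4e-09), with -11.27 without KO A17 and -11.29 without KO A18. The cancer-testis antigen genes MAGEA4 and MAGEA8 fell from 194 to 0.114 CPM and from 19.7 to 0.0222 CPM. The MAGEA4 fold change was -10.63, or -12.29 without KO A1, and its call was lost with DESeq2 (adjusted p = 0.0741). CWH43, involved in lipid remodelling of membrane anchors, and RIPOR2, a RhoA regulator gene, had log2 fold changes of -8.96 (SE 0.98) and -8.61 (SE 0.92).

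In the other direction, SPAG16, a sperm axoneme gene, rose from 0.0570 to 7.16 CPM (log2 fold change 6.93, adjusted p = 2.5e-06). SDK1, a cell adhesion gene, rose from 0.0900 to 9.17 CPM (log2 fold change 6.69, adjusted p = 4.3e-05), and P2RY1, a purinergic receptor gene, from 0.430 to 38.8 CPM (log2 fold change 6.52, adjusted p = 0.000344). GUCY1A2, a subunit gene of soluble guanylate cyclase, rose from 0.432 to 27.5 CPM (log2 fold change 6.03, adjusted p = 0.000824). DAPK1, a death-associated kinase gene, rose from 0.639 to 23.6 CPM (log2 fold change 5.23, adjusted p = 0.00295), and DNER, which encodes a Notch ligand, from 0.209 to 7.33 CPM (log2 fold change 5.14, adjusted p = 0.000597). These 6 fold changes depended on the library labelled WT A12 and without it were 7.75, 8.96, 8.93, 9.24, 8.41 and 6.75. UCHL1, a neuronal deubiquitinase gene, varied widely among KO tumours (26.9 ± 34.4 CPM against 0.280 ± 0.313 in WT), with a log2 fold change of 6.54, or 5.80 without KO A13. TENM1, a teneurin gene, rose from 3.63 ± 3.23 to 115 ± 95.0 CPM (log2 fold change 4.99, SE 0.68, adjusted p = 7.4e-05). Other genes with small adjusted p-values mostly moved less. KCNMA1, the BK potassium channel gene, rose from 41.4 ± 12.4 to 274 ± 75.8 CPM (log2 fold change 2.72, SE 0.20, adjusted p = 9.9e-08). ACVR2A, an activin receptor gene, POTEF and EXTL2, a heparan sulfate glycosyltransferase gene, rose by 1.60, 2.70 and 1.38 on the log2 scale. RAPGEF3, which encodes the cAMP-activated exchange factor EPAC1, fell to 3.69 ± 0.749 CPM in KO (log2 fold change -2.44, SE 0.22, adjusted p = 1.7e-06). MAPK13, a p38 kinase gene, LINC01619 and TMC6 had log2 fold changes of -6.66, -6.02 and -1.27. MT1G, MAGEA4, MAGEA8, H2AJ and POTEF belong to families of near-identical genes, and the handling of shared reads was not given in the sources used here, so the split among their members is uncertain.

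**Figure D3:**
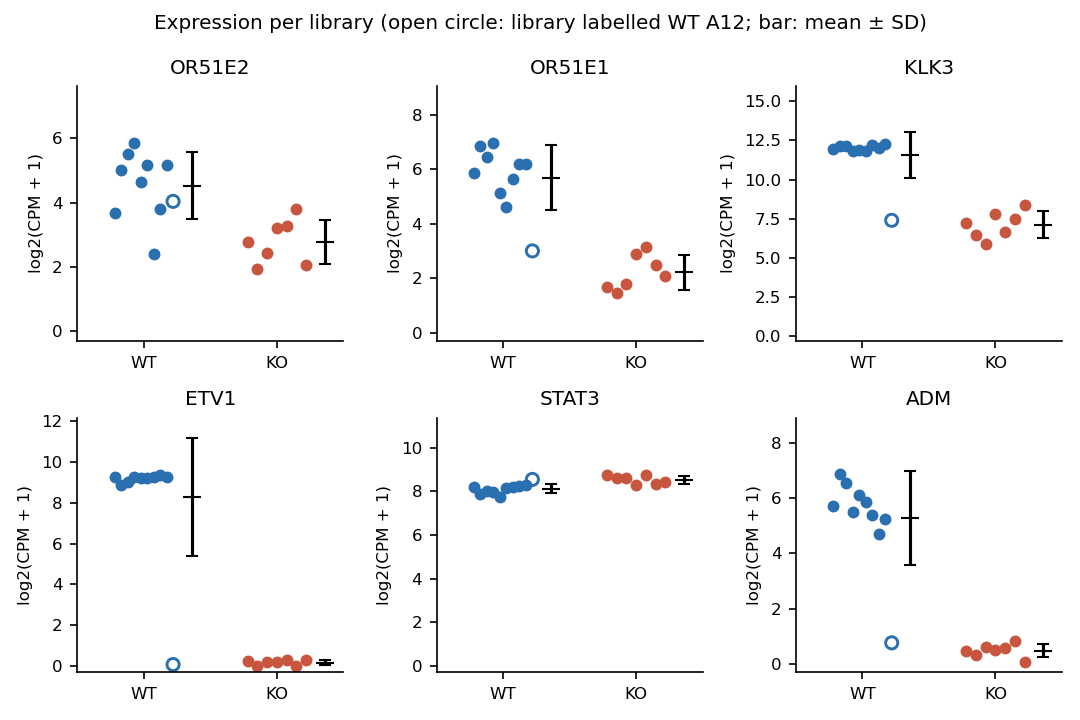
Expression of OR51E2, OR51E1, KLK3, ETV1, STAT3 and ADM on a log2(CPM + 1) scale (y axis), one point per library, with WT in blue, the library labelled WT A12 as an open circle and KO in red, and bars giving mean ± SD of the plotted values. A12 lies within the KO range for OR51E1, KLK3, ETV1, STAT3 and ADM. For OR51E2 it lies above the KO range, and levels of the groups overlap.

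STAT3 itself was moderately higher in KO. It rose from 282 ± 44.3 to 373 ± 48.8 CPM (log2 fold change 0.41, SE 0.11, adjusted p = 0.00638). IL6ST, the shared receptor chain of interleukin 6 type cytokines, was at 139 ± 22.2 CPM in WT and 157 ± 29.4 in KO (adjusted p = 0.293), and JAK1 at 8.45 ± 2.02 and 9.29 ± 1.79 (adjusted p = 0.577). SOCS3, a feedback inhibitor induced by STAT3, had at most 24 counts in a library and was not tested. Among 30 tested STAT3 targets, 6 rose and 11 fell (6 and 13 adjusted over the list alone), with a median log2 fold change of -0.27. The list did not pass the set test against other genes (camera, adjusted p = 0.0934, and adjusted p = 0.693 with an estimated correlation). PIM1, a kinase gene induced by STAT3, fell from 45.7 ± 18.8 to 5.88 ± 1.73 CPM (log2 fold change -2.96, SE 0.32, adjusted p = 1.0e-05). TWIST1, a mesenchymal transcription factor gene, fell from 18.6 to 0.136 CPM (log2 fold change -7.09, adjusted p = 2.7e-05), with a fold change of -8.01 without KO A17. The receptor genes IL6R and OSMR rose from 53 to 108 CPM (log2 fold change 1.02, adjusted p = 0.000681) and from 4.09 to 9.47 CPM (log2 fold change 1.21, adjusted p = 0.000948). Of 39 tested JAK-STAT pathway components, 10 rose and 3 fell (11 and 4 adjusted over the list alone, camera adjusted p = 0.0699), and the list was called higher without KO A16 (adjusted p = 0.0396) and not with an estimated correlation (adjusted p = 0.693). SOCS2, a feedback inhibitor of cytokine receptors, rose from 9.00 ± 3.60 to 37.5 ± 15.9 CPM (log2 fold change 2.06, SE 0.25, adjusted p = 1.6e-05). IL4R, the interleukin 4 receptor gene, fell from 8.76 to 4.45 CPM (log2 fold change -0.98, adjusted p = 0.000480). STAT2 and JAK2, singled out after their values were seen, rose by 0.45 and 0.73 on the log2 scale.

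Androgen-responsive genes moved in both directions. Of 38 tested androgen-induced genes, 14 rose and 15 fell (15 and 16 adjusted over the list alone, camera adjusted p = 0.823). KLK3 fell from 3774 ± 1358 to 159.8 ± 93.6 CPM (log2 fold change -4.56, SE 0.55, adjusted p = 2.7e-05). ALDH1A3, a retinaldehyde dehydrogenase gene, fell from 181 to 81.9 CPM (log2 fold change -1.15, adjusted p = 8.2e-06). HERC3, a ubiquitin ligase gene, and TUBA3D, a tubulin gene with near-identical copies, rose from 298 to 891 CPM (log2 fold change 1.58, adjusted p = 1.4e-05) and from 9.71 to 46.6 CPM (log2 fold change 2.26, adjusted p = 1.0e-05). KLK2, ACP3, which encodes prostatic acid phosphatase, and TMPRSS2 were singled out after their values were seen and had log2 fold changes of -2.39, -4.43 and -1.16. Of 20 tested androgen-repressed genes, 4 rose and 9 fell, also when adjusted over the list alone (camera adjusted p = 0.129). PEG3, an imprinted zinc finger gene, fell from 1999 to 41.3 CPM (log2 fold change -5.60, adjusted p = 2.7e-05), and CAMK2N1, which encodes an inhibitor of calmodulin-dependent kinase, from 610.5 to 9.20 CPM (log2 fold change -6.05, adjusted p = 0.000103). IGF1R, the receptor for insulin-like growth factor, rose from 32.8 to 287 CPM (log2 fold change 3.13, adjusted p = 7.4e-05). It was at 131 CPM in the library labelled WT A12, without which the WT mean was 21.9 CPM and the log2 fold change 3.70. NTS, which encodes neurotensin, went from 3.27 CPM to no count in KO, at least 322-fold lower by the same floor. Of 17 tested genes of steroid metabolism, 4 rose and 5 fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.905), and the median and the test pointed down while the mean was above 0. SULT2B1 and SRD5A3 fell (log2 fold change -1.06, SE 0.20, adjusted p = 0.000683) and (log2 fold change -0.60, SE 0.13, adjusted p = 0.00203), and STS rose (log2 fold change 0.80, SE 0.21, adjusted p = 0.00685). AKR1C1 rose by 3.28, or by 5.01 without the library labelled WT A12, and shares sequence with other AKR1C genes.

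Genes of hypoxia and glycolysis fell in KO, and of the 32 lists tested this one had the smallest camera p. Of 40 members, 28 fell and 2 rose (29 and 2 adjusted over the list alone), with a median log2 fold change of -0.83 (camera, adjusted p = 3.0e-08). This call was lost with an estimated correlation (adjusted p = 0.693 with an estimated correlation), and without the library labelled WT A12 the list had 29 falls and 2 rises. ADM, which encodes the hypoxia-induced peptide adrenomedullin, fell from 53 ± 32.6 to 0.416 ± 0.225 CPM (log2 fold change -7.00, SE 0.79, adjusted p = 1.7e-05). EGLN3, an oxygen-sensing hydroxylase gene, fell from 55.3 ± 17.7 to 18.3 ± 4.83 CPM (log2 fold change -1.59, SE 0.21, adjusted p = 2.7e-05), and INSIG2, a regulator of sterol synthesis, from 85.8 to 33.0 CPM (log2 fold change -1.38, adjusted p = 2.4e-05). SLC2A3, a glucose transporter gene, rose from 0.624 to 3.38 CPM (log2 fold change 2.43, adjusted p = 0.00319). CA9, VEGFA, LDHA and PGK1 were singled out after their values were seen and had log2 fold changes of -5.50, -1.55, -1.02 and -0.91. Some proliferation genes were also lower, with smaller median changes over their lists than over the hypoxia list. Of 45 S phase genes, 20 fell and 1 rose (22 and 1 adjusted over the list alone, median -0.29, camera adjusted p = 1.1e-04, and adjusted p = 0.693 with an estimated correlation). WDR76 fell from 24.5 to 9.46 CPM (log2 fold change -1.38, adjusted p = 0.000258), UHRF1, which maintains DNA methylation, from 66.4 to 36.1 CPM (log2 fold change -0.88, adjusted p = 0.000337), and E2F1 from 72.8 to 44.0 CPM (log2 fold change -0.72, adjusted p = 0.000599). CDCA7 rose from 17.2 to 28.4 CPM (log2 fold change 0.72, adjusted p = 0.00102). Of 52 G2 and M phase genes, 15 fell and none rose, also when adjusted over the list alone (median -0.22, camera adjusted p = 7.1e-04, and adjusted p = 0.693 with an estimated correlation). MKI67, the Ki-67 proliferation marker gene, fell from 134 ± 34.6 to 86.7 ± 11.2 CPM (log2 fold change -0.63, SE 0.15, adjusted p = 0.00342), and NDC80, CCNB2 and GTSE1 by 0.61, 0.61 and 0.52 on the log2 scale. Hypoxia, S phase and G2 and M phase were the 3 of 32 tested lists called, and 81 of 100 random splits of the same libraries, the real one included, called at least as many. The share of counts on mitochondrial ribosomal RNA differed between the groups, 1.00 ± 0.457% in WT and 1.59 ± 0.196% in KO (two-sided exact permutation test, p = 0.00874), while that on mitochondrial mRNA was 3.52 ± 1.58% and 4.48 ± 0.633% (p = 0.155, same exact test). The same test gave p = 0.106 for the number of genes with a count and p = 0.144 for the share on the most abundant genes. These p-values were not adjusted for the number of measures.

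**Figure D4:**
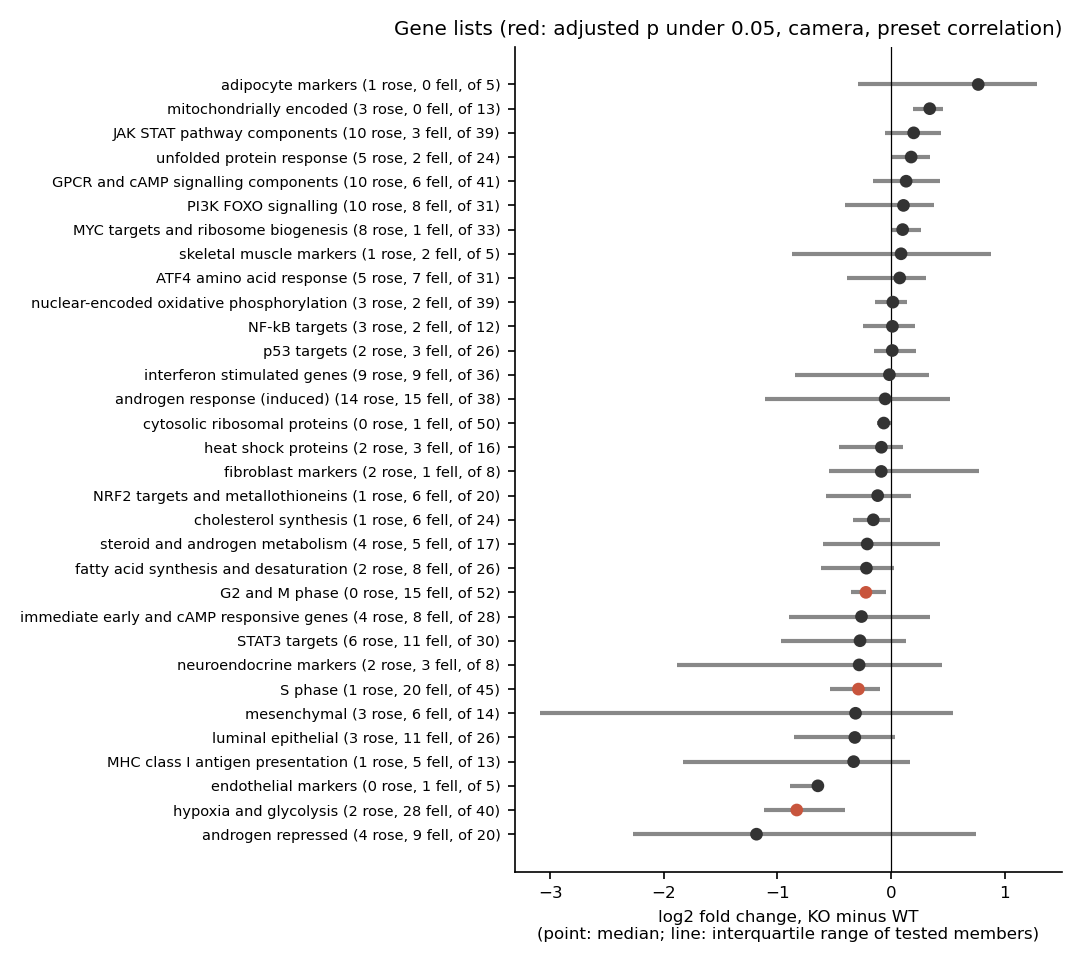
Median (point) and interquartile range (line) of the log2 fold change (KO minus WT, x axis) over the tested members of each of 32 gene lists, with the number of members that rose or fell after each name. The 3 lists in red, hypoxia and glycolysis, S phase and G2 and M phase, had an adjusted p under 0.05 with camera's preset correlation, and none did with an estimated one.

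Of 26 tested genes of fatty acid synthesis and desaturation, 8 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 0.0567). The list was called lower without WT A7 (adjusted p = 0.0247), WT A8 (0.0411), WT A10 (0.0493), KO A13 (0.0468) or KO A1 (0.0485), with the log2 total count as covariate (0.0383) and without WT A5, A7, A12 and KO A18 (0.0437). With an estimated correlation it was not called (adjusted p = 0.693). SCD5, a desaturase gene, fell from 20.1 to 1.55 CPM (log2 fold change -3.69, adjusted p = 5.1e-05). PLIN2, a lipid droplet protein gene, and ACSL1, an acyl-CoA synthetase gene, had log2 fold changes of -3.96 and -0.87, while ACSL4 rose by 1.90. Of 24 genes of cholesterol synthesis, 6 fell and 1 rose (7 and 2 adjusted over the list alone, camera adjusted p = 0.120), and without the library labelled WT A12 9 fell and 2 rose. TM7SF2, EBP and ACAT2 fell by 0.87, 0.42 and 0.44 on the log2 scale. Of 13 mitochondrially encoded genes, 3 rose and none fell (2 and none adjusted over the list alone, camera adjusted p = 0.0567). This list was called higher without WT A7 (adjusted p = 1.4e-04), WT A10 (0.0493), KO A13 (0.0468), KO A16 (0.0320), KO A18 (0.0370) or KO A1 (0.0485), but not with an estimated correlation (0.738) or fry (0.126). It was also called with the log2 total count as covariate (0.00483) and without WT A5, A7, A12 and KO A18 (9.0e-05). COX3, ND1 and ND3, subunit genes of the respiratory chain, rose by 0.64, 0.83 and 0.59 on the log2 scale. The COX3 call was lost without KO A13 or A15, the ND1 call without WT A4 or A9 or KO A15 or A16, and the ND3 call without WT A2, A3, A4, A5, A8, A9 or A10 or KO A13, A14, A15, A17 or A1, with adjusted p of at most 0.0593, 0.0676 and 0.106. Of 39 nuclear-encoded genes of oxidative phosphorylation, 3 rose and 2 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.966), among them ATP5MC1 (log2 fold change 0.50, SE 0.11, adjusted p = 0.00152) and UQCRC1 (log2 fold change -0.36, SE 0.09, adjusted p = 0.00569).

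Of 50 ribosomal protein genes, 1, RPLP1 (log2 fold change -0.41, SE 0.12, adjusted p = 0.0153), fell and none rose (none either way adjusted over the list alone, camera adjusted p = 0.304). Without the library labelled WT A12 the list had 7 falls and no rise, or 1 fall and no rise adjusted over the list alone. Of 33 MYC targets and ribosome biogenesis genes, 8 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.214), and without that library 9 rose and 2 fell. POLR1A and POLR1B, subunit genes of RNA polymerase I, rose by 0.52 and 0.48, and GNL3, which encodes nucleostemin, fell by 0.35.

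Interferon and antigen presentation genes were mixed. Of 36 interferon-stimulated genes, 9 rose and 9 fell, also when adjusted over the list alone (camera adjusted p = 0.708). RSAD2, an antiviral enzyme gene, and UBE2L6, an ISG15 conjugating enzyme gene, fell from 6.24 to 0.755 CPM (log2 fold change -3.06, adjusted p = 0.000159) and from 4.15 to 0.416 CPM (log2 fold change -3.30, adjusted p = 0.000136). IFIT5 fell by 1.32 and IFITM1 rose by 1.78 on the log2 scale. Of 13 genes of MHC class I presentation, 5 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.304), and without the library labelled WT A12 6 fell and 2 rose. NLRC5, the class I transactivator gene, fell from 12.9 ± 3.93 to 3.45 ± 0.717 CPM (log2 fold change -1.90, SE 0.22, adjusted p = 1.0e-05). HLA-B and HLA-C, which share sequence, had log2 fold changes of -1.83 and -1.19, and ERAP1, a peptide-trimming protease gene, rose by 0.78. Of 12 NF-kB targets, 3 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.966), with a median above 0 and a test direction of down. BIRC3, an apoptosis inhibitor gene, fell from 40.0 to 15.8 CPM (log2 fold change -1.34, adjusted p = 0.000661) and SOD2 by 0.52, while TNFAIP3 and TNFAIP2 rose by 1.04 and 1.17.

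Camera called none of the stress lists. GDF15, a stress-induced cytokine gene on the p53 list, fell from 3235 ± 1402 to 213 ± 95.8 CPM (log2 fold change -3.92, SE 0.46, adjusted p = 1.8e-05). On that list of 26, 3 fell and 2 rose (3 and none adjusted over the list alone, camera adjusted p = 0.966), the median lay above 0 and the mean and test below, and without the library labelled WT A12 4 fell and 1 rose. TP53INP1 and DDB2 fell by 0.71 and 0.42. Of 31 genes of the ATF4 amino acid response, 7 fell and 5 rose, also when adjusted over the list alone (camera adjusted p = 0.966), with a mean below 0 and a median and test above. NUPR1, a stress-induced nuclear protein gene, fell from 358 to 98.5 CPM (log2 fold change -1.86, adjusted p = 9.2e-05) and SLC7A5 by 1.28, while CTH and PYCR1 rose by 0.89 and 0.57. Of 24 genes of the unfolded protein response, 5 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.120). Leaving out the library labelled WT A12 brought this to 10 and 2. CREB3L2, PDIA4 and ERN1 rose by 0.67, 0.60 and 0.49, and SELENOK fell by 0.39. Of 16 heat shock protein genes, 2 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.823), or 2 and 5 without that library, among them HSPA4L (log2 fold change 1.48, SE 0.25, adjusted p = 0.000305) and HSPB1 (log2 fold change -1.06, SE 0.20, adjusted p = 0.000578). Of 20 NRF2 targets and metallothioneins, 6 fell and 1 rose (7 and 1 adjusted over the list alone, camera adjusted p = 0.268), or 7 and 3 without that library. NQO1, a quinone reductase gene, fell from 78.4 to 27.1 CPM (log2 fold change -1.53, adjusted p = 0.000121), and MT1F by 1.29.

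Of 26 luminal epithelial genes, 11 fell and 3 rose, also when adjusted over the list alone (camera adjusted p = 0.0567). The list was called lower without WT A7 (adjusted p = 0.0468), WT A10 (0.0493), KO A13 (0.0468) or KO A1 (0.0485), but not with an estimated correlation (0.693). It was also called with the log2 total count as covariate (0.0466) and without WT A5, A7, A12 and KO A18 (0.0330). GATA2, a transcription factor gene, fell from 268 to 117 CPM (log2 fold change -1.19, adjusted p = 0.00107), and CLDN4, a tight junction gene, from 338 to 154 CPM (log2 fold change -1.14, adjusted p = 0.000334). CDH3, the P-cadherin gene, rose by 3.43, or by 4.72 without the library labelled WT A12. Of 14 mesenchymal genes, 6 fell and 3 rose, also when adjusted over the list alone (camera adjusted p = 0.214). CCN1 fell from 20.9 to 9.13 CPM (log2 fold change -1.19, adjusted p = 4.5e-05), and TGFB2 fell by 3.51, while TGFBI rose by 3.56, or by 5.11 without that library. Of 8 neuroendocrine markers, 3 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 0.373). SYT1, a synaptic vesicle gene, and ENO2, a neuronal enolase gene that is also glycolytic, fell by 3.30 and 1.42, NTS was without a count in KO, and UCHL1 rose, as given above.

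Among signalling genes, 10 of 41 tested members of G protein and cAMP signalling rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.325). Besides RAPGEF3, GRK2, a receptor kinase gene, and PRKACB, a catalytic subunit gene of protein kinase A, fell by 0.72 and 0.75, and GNAQ, a G protein subunit gene, rose from 9.29 to 34.2 CPM (log2 fold change 1.88, adjusted p = 0.000193). Of 28 immediate early and cAMP-responsive genes, 8 fell and 4 rose (9 and 4 adjusted over the list alone, camera adjusted p = 0.214). NR4A1, DUSP5 and DUSP1 fell from 68.8 to 18.5 CPM (log2 fold change -1.89, adjusted p = 0.000305), from 17.9 to 3.47 CPM (log2 fold change -2.37, adjusted p = 0.000290) and from 119 to 38.1 CPM (log2 fold change -1.64, adjusted p = 0.000371), and KLF6 rose by 0.64. Of 31 PI3K and FOXO signalling genes, 10 rose and 8 fell (12 and 8 adjusted over the list alone, camera adjusted p = 0.534). CCNG2, a FOXO target gene, fell from 388 to 113 CPM (log2 fold change -1.78, adjusted p = 1.7e-05) and PIK3CD by 0.47, while PHLPP1, a phosphatase gene of AKT, rose by 0.63. Of the genes on the olfactory receptor list, 3 were tested, too few for a set test: OR51E1 and OR51E2 fell, and OR2A7 rose by 1.08, a call lost without WT A9, KO A13 or KO A18 (adjusted p up to 0.0789), with the same calls adjusted over the list alone. OR51D1, lower in KO as given above, was not on that list.

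Markers of host cells were kept as a check on residual mouse reads. Of 8 tested fibroblast markers, 2 rose and 1 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.966), with a mean above 0 and a median and test below, and without the library labelled WT A12 2 rose and 2 fell. COL6A2 rose from 76.3 to 179 CPM (log2 fold change 1.23, adjusted p = 0.000912), COL3A1 fell from 2.86 to 0.948 CPM (log2 fold change -1.59, adjusted p = 0.00118), and COL5A1 rose by 2.29, or 1.69 without KO A1. Of 5 endothelial markers, VWF fell from 23.2 to 6.12 CPM (log2 fold change -1.92, adjusted p = 0.000136) and none rose, also when adjusted over the list alone (median log2 fold change -0.64, camera adjusted p = 0.214). With fry this list was called lower (adjusted p = 0.0359), and with an estimated correlation it was not (0.693). Of 5 skeletal muscle markers, TTN rose by 0.88 and MB and NEB fell by 1.10 and 0.87, also when adjusted over the list alone (camera adjusted p = 0.900), with a median above 0 and a mean and test below. Of 5 adipocyte markers, CFD rose by 2.06 (2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.815). CFD was at 0.722 ± 0.415 CPM in KO, and its fold change was 3.02 without the library labelled WT A12, while its call held in only 3 of the 17 fits that left out 1 library, those without WT A11, the library labelled WT A12 or KO A18 (adjusted p up to 0.104 in the others). Of 2 tested keratinocyte markers, KRT14 fell from 2.86 to 0.775 CPM (log2 fold change -1.88, adjusted p = 0.00186), also when adjusted over the list alone. None of 4 tested macrophage and neutrophil markers changed, also when adjusted over the list alone, while without the library labelled WT A12 CSF1R, singled out after its values were seen, was called higher (log2 fold change 1.62, adjusted p = 0.0427, against 0.0504 with it). No erythroid marker had enough counts to be tested.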

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

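The tests of position on genes lower in KO, of a mixture, of a swap, of other splits, of a clone difference and of the OR51 neighbourhood were chosen after the results were seen. The tests of position on genes higher in KO, of genes silent in KO and of copy number were set before their values were seen.

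In 284 groups of values, 51 had a highest or lowest library set apart from the rest by a gap that was large against the group's range. For independent, normally distributed values chance gives about 1 in 20 groups. Most groups here were CPM values of genes named because KO and WT differed. They are not independent, so that rate is not a fair yardstick, and flags of the same library repeat each other. The library labelled WT A12 accounted for 31 of the 51. Its gap was 0.841 of the WT range on the first principal component. Among genes on which it was the lowest WT library, the gap was 0.7 of the range for KLK3, 0.573 for ERVMER34-1, 0.717 for ETV1, 0.766 for MAGEA4, 0.505 for MAGEA8, 0.612 for RIPOR2, 0.706 for MAPK13, 0.473 for CAMK2N1, 0.584 for IFIT5 and 0.533 for GNL3. Among genes on which it was the highest, the gap was 0.869 for SDK1, 0.925 for P2RY1, 0.969 for GUCY1A2, 0.939 for DAPK1, 0.836 for DNER, 0.635 for ACVR2A, 0.561 for EXTL2, 0.626 for TUBA3D, 0.905 for IGF1R and 0.543 for ERAP1. It was also 0.779 for CTH, 0.552 for PDIA4, 0.771 for HSPA4L, 0.503 for HSP90AA1, 0.57 for KLF6, 0.828 for CDH3, 0.862 for TGFBI, 0.824 for AKR1C1, 0.545 for GNAQ and 0.626 for CFD.

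A mislabelled sample, a KO tumour under a WT label, is a candidate explanation for the place of A12. OR51E2 itself does not favour it. At 15.5 CPM in A12, it was above each KO library (2.81 to 12.9) and within the range of the other WT libraries (4.28 to 57.5). This is 1 gene, and its levels overlap between the groups. On a scale where the other WT libraries average 0 and the KO libraries 1, with the scored library held out, A12 stood at 0.886 on genes lower in KO (KO libraries 0.820 to 1.02, other WT -0.0141 to 0.0958) and at 0.862 on genes higher in KO (KO 0.769 to 1.13, other WT -0.0540 to 0.243). A swap with a KO library is argued against by the lowest KO position, 0.840, and a mixture of WT and KO cells by genes silent in KO, which stood in A12 at a median of 1.57% of the other WT level. A mixture would need 38.9%, given the level in A12 of genes silent in the other WT libraries, and all 36 genes were below that. Of these 36 genes, 13.9% reached 1 CPM in A12, MT1G among them, against 0 to 12.2% (SD 5.05) in each KO library held out, which leaves a KO tumour and a related line both open; the series text counts 1 WT tumour fewer and 1 KO tumour more than the labels, and a biological alternative, a WT tumour grown from a subclone of the parental cells close to the KO clone, stays open and untested.

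The second pattern is the number of genes that differ, 5563 in all and 2314 over 2-fold. For each count 1 of 100 splits of the libraries, the real one, gave as many, so a random grouping of these tumours is unlikely to give it. The splits exchange tumours, so they cannot show whether another clone would differ as much from the parental cells. The highest other split gave 3535 and 1406 genes. That split set 7 WT libraries against 3 WT, A12 among them, and 7 KO libraries, so it follows the structure of the samples, and 98 of the other splits called no gene. Differences in copy number between the lines as the main cause are argued against by position. Bins of 20 Mb explained 10.3% of the variance of ranked fold changes among 5376 called genes, 7.37 percentage points above the mean of shuffled gene orders. Shuffled orders gave 2.93% on average and at most 4.16% over 1000 shuffles, so the changes did cluster by position in part. A smaller contribution of copy number therefore stays open. A difference between the KO clone and the parental cells that is unrelated to OR51E2 cannot be told apart from the knockout, because all KO tumours come from 1 clone, and 31 of the 36 genes silent in KO were also under 1 CPM in A12.

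The third pattern is the fall of genes next to OR51E2. A fall limited to the targeted gene is argued against, since 4 of the 5 other tested genes within 100 kb were lower by more than 1 on the log2 scale. Lower transcription of the neighbourhood is a candidate explanation, with a median log2 fold change of -2.40 for these genes, against -0.21 for the genes from 100 kb to 1 Mb. All 5 lie at lower coordinates than OR51E2. On its other side the nearest tested gene, UBQLNL, is 816540 bases away, so a fall within 100 kb on that side could not be seen. UBQLNL was low, at 0.496 CPM in WT and 0.138 in KO. Its log2 fold change was -1.80 (SE 0.74, edgeR adjusted p = 0.0715), or -1.94 without the library labelled WT A12 (adjusted p = 0.0387). Further out on that side, TRIM5 and TRIM22 had log2 fold changes of -0.08 and 1.03. Whether the edit itself, the clone or a regulator of this region accounts for the fall was not tested.

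Other libraries stood apart on single measures. WT A7 was highest in its group for the mitochondrial mRNA share (7.60%, gap 0.533 of the range), the third principal component (0.503) and MT1G (0.5). WT A5 was lowest on the second component (0.495). KO A18 was lowest on the second component (0.759) and for CLDN4 (0.589), and highest on the third component (0.769) and for SOD2 (0.727) and ACAT2 (0.593). KO A1 was highest for MAGEA4 (0.79) and DUSP1 (0.738) and lowest for DDB2 (0.598). KO A17 was highest for TWIST1 (0.775), and KO A13 for TENM1 (0.609) and IL4R (0.587). KO A14 was highest for TGFBI (0.588) and KO A16 lowest for GNAQ (0.579). In WT, A8 was highest for TNFAIP3 (0.479), A3 for CHORDC1 (0.505) and A11 for NQO1 (0.516).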

How the results depend on the processing

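The fit without WT A5, A7, A12 and KO A18 was chosen after the data were seen, and all other alternatives before. The count of changed genes, 5563, ran from 4882 to 6441 when 1 library was left out and from 5121 to 8102 under other scalings, filters, tools and the depth covariate, and no called gene shared between the settings had the opposite sign. The count over 2-fold, 2314, ran from 2141 to 2704 with 1 library left out and from 1759 with the stricter filter, where 14598 genes were tested, to 3404 without a filter, where 37061 were. OR51E2 was lower in all settings, with a log2 fold change of -2.30 to -1.86 when 1 library was left out. The number of lists called, 3, was 6 with the log2 total count as covariate, 0 with an estimated correlation, 15 with fry, 6 without WT A5, A7, A12 and KO A18, and 3 to 6 with 1 library left out. It was 6 without WT A7, WT A10, KO A13 or KO A1, 5 without KO A16 and 4 without WT A8 or KO A18. The lists gained at 6 were the mitochondrially encoded, the fatty acid and the luminal epithelial lists, without KO A16 the mitochondrially encoded list and the JAK-STAT components (adjusted p = 0.0396), without WT A8 the fatty acid list and without KO A18 the mitochondrially encoded list. With fry, the G2 and M phase list was lost (adjusted p = 0.0528), and 13 lists were gained. They were the fatty acid, JAK-STAT component, neuroendocrine, GPCR, luminal epithelial, NRF2, mesenchymal, androgen-repressed, STAT3 target, MHC class I, endothelial, unfolded protein response and cholesterol lists, with adjusted p from 0.00400 to 0.0477. Of the random splits of the libraries, 81 of 100 called at least 3 lists and the highest other called 16, so chance is not excluded for this count. The STAT3 targets list reached an adjusted p of 0.0258 with fry, which does not compare a list with other genes, and had 0.0604 to 0.141 with 1 library left out, and the androgen response list 0.386 to 0.965. The causes were not tested.

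For the named genes, 954 values under alternatives other than leaving a library out stayed on the same side of the threshold with the same direction and 15 lost the call. With 1 library left out 2413 stayed and 89 lost it. The calls lost included those of CFD, COX3, MAGEA4, ND1, ND3, NDUFV1, OR2A7, TFB2M, UQCRQ and ZMAT3, and no named gene turned direction. At this depth SOCS3, with 110 counts over all libraries, could not be tested, and in simulated data 21% of 2-fold changes were missed among genes with a mean of at least 1 CPM.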

Other observations

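The test of the MAGEA family was chosen after the result was seen, as were the genes named in this part.

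The MAGEA cancer-testis antigen genes of chromosome X had unequal fold changes. Of 9 tested members, 5 were called lower, MAGEA1, MAGEA2, MAGEA4, MAGEA8 and MAGEA10, the last from 128 to 5.67 CPM (log2 fold change -4.50, SE 0.48, adjusted p = 1.1e-05). MAGEA3 was at 167 CPM in WT and 154 in KO (adjusted p = 0.324), and MAGEA6 and MAGEA12 at 89.6 and 72.5 CPM in WT and 84.5 and 63.4 in KO, and none of these 3 passed the test (log2 fold changes -0.12, -0.08 and -0.19, SE 0.09 each). MAGEA2B, at 6.86 CPM in WT and 7.10 in KO, was the only member with a fold change above 0 (log2 fold change 0.05, SE 0.19, adjusted p = 0.873). Counts of members left open whether the family fell as a whole, since 5 of 9 were called lower and only MAGEA2B lay above 0. A fall of similar size in every member is argued against by MAGEA3, MAGEA6 and MAGEA12, which kept most of their WT level in KO. Reads of near-identical members can be shared among them, so the split among those members is uncertain.

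Leaving out the library labelled WT A12, 36 genes with at least 5 CPM in the WT mean were under 1 CPM in each KO library, and 35 genes with at least 5 CPM in the KO mean were under 1 CPM in each of these WT libraries. The first set lay on 15 chromosomes and the second on 20. MEST, an imprinted gene, went from 41.0 CPM in these WT libraries to 0.145 in KO. LACC1 and CCDC122, neighbours on chromosome 13, went from 0.0390 to 22.4 CPM and from 0.00221 to 12.3. A12 was at 27.3 and 13.9 CPM for these 2 genes, and at 0.0917 for MEST. Over the 35 genes A12 stood at a median of 61.1% of the KO mean, from 2.95% for the lowest, while it was at 3.70 CPM for P2RY1 against 38.8 in KO and at 0.795 for UCHL1 against 26.9.

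Chromosome 13 was picked after the values of all chromosomes were seen. It held 178 tested genes with at least 5 CPM in the KO mean and in the WT mean without A12. Their median log2 difference from the mean of the other WT libraries was 0.24 in KO (SD 0.165, from 0.0460 to 0.54). It was 0.45 in A12 and -0.0865 to 0.247 in the other WT libraries, so the groups overlapped.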
